A study of Mus musculus with 9 samples.

How the data were processed

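RNA sequencing measured gene expression in wild-type mouse bone marrow-derived macrophages (BMDM). Per the labels' protocols, bone marrow from male mice 6 to 12 weeks old was grown in medium with fetal bovine serum and given M-CSF, the growth factor that drives macrophage differentiation, at 25 ng/mL over 6 days. The macrophages were then treated for 18 hours with exosomes, small vesicles released by cells, at 2e+09 particles/mL, or with PBS, the vehicle. The exosomes came from BMDM of ApoE-deficient mice or from BMDM of wild-type mice. Each of the 3 groups had 3 libraries, which the design text calls biological replicates. No source used here says whether the replicates came from separate mice or whether they received separate exosome preparations, so the p-values measure the spread between these libraries.

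The deposited table holds raw counts per Ensembl gene, with a column per library and no pooled column. Total RNA was extracted with a column kit and libraries were made with an mRNA kit, per the labels' protocols. STAR 2.7.5c and the mouse build GRCm38 are named in the submitters' processing notes. The annotation release, the strand setting of the counting and any read trimming are not given in the sources used here. The table lists 55536 gene IDs, of which 55450 matched a symbol in the GENCODE M21 annotation of GRCm38 and 86 did not. No row held unassigned reads or totals. Because the use of strand in counting is not stated, reads from overlapping genes cannot be assigned with certainty, and the share of a gene's exon length that overlaps exons of other genes was computed from GENCODE M21. Of the mitochondrial mRNAs, mt-Co2, mt-Atp6, mt-Atp8 and mt-Nd4l were listed at 0 in all 9 libraries, mt-Co3 at 0 to 1 and mt-Nd3 at 0 to 7, whereas mt-Co1 had 214325 to 273895 counts per library. The mitochondrial mRNA list therefore rests on 7 of its 13 genes.

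The total count per library was 28581306 to 35929596, with 17150 to 18680 genes detected. The 10 most abundant genes of a library took 11.9% to 12.8% of its counts, protein-coding genes 98.7% to 99.0%, and mitochondrial genes 1.77% to 2.08%. TMM factors lay between 0.995 and 1.01. To look for a library deposited more than once, counts of each pair of libraries were compared by chi-square over genes. The statistic per gene was 6.85 to 10.4 within groups and 7.84 to 19.1 between groups, so every pair differed by more than sampling noise and all 9 libraries were kept.

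Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr at a minimum count of 10, which left 13815 genes, and libraries were scaled with TMM factors. A quasi-likelihood model with robust dispersion and the group as its only term was fitted to all 9 libraries, so that the groups shared an estimate of the spread. The biological coefficient of variation was 12.0%. Contrasts compared ApoE-deficient exosomes with PBS, wild-type exosomes with PBS, and ApoE-deficient with wild-type exosomes. An F test asked whether a gene differed among any of the groups. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05, and "adjusted p" of a gene means this edgeR value throughout. Standard errors of log2 fold changes were derived from the F statistics. The SE of a median over a set of genes came from the spread between those genes. It treats the genes as independent and does not measure the spread between libraries. CPM values are normalised with TMM factors and given as mean ± SD over 3 libraries. With 3 libraries against 3, an exact permutation test of a single gene cannot go below p = 0.1, so none is given.

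The gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The 38 gene lists came from textbook knowledge, covering metabolism, inflammation, stress responses and macrophage biology as well as markers of other cell types. Lists with at least 3 genes tested were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list moves on balance in a direction, were run beside it. The T and NK cell list and the mast cell and basophil list had 2 genes each past the filter and were not tested.

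Genes named in the text followed a rule. For each comparison these were the 10 with the highest and the 10 with the lowest log2 fold change among genes with an adjusted p under 0.05, a mean of at least 5 CPM, complete separation of the libraries of the groups, which chance gives for 10% of unchanged genes, and a symbol that is not a predicted gene. In each list up to 4 members with the lowest p could be named, and Apoe was named in every comparison. Other genes are identified where they appear as chosen after their values were seen.

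The edgeR, DESeq2 and camera steps were tested on simulated counts with 50 genes changed at each of 4 fold sizes. For ApoE-deficient exosomes against PBS, with 13414 genes tested, 32% of genes changed 1.2-fold, 62% at 1.5-fold, 86% at 2-fold and 92% at 3-fold were recovered. For wild-type exosomes against PBS, also with 13414 genes, the shares were 54%, 70%, 86% and 92%. For ApoE-deficient against wild-type exosomes, with 13418 genes, they were 42%, 74%, 90% and 90%. False calls made up 5.56%, 6.21% and 8.64% of all calls in these simulations, in the same order.

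The alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, total counts without TMM factors, no filter on low counts, a mean of at least 5 CPM, a fit to the 6 libraries compared, the replicate number as a block, and leaving out each library in turn. Correlation, covariance and overlap of the comparisons with PBS were set beside 40 simulations of groups with no effect, since both use the same PBS libraries. For the overlap these show chance without any effect only. Figures were drawn with matplotlib 3.10.9.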

Results

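The data are 9 RNA-seq libraries of wild-type BMDM, 3 treated for 18 hours with exosomes from ApoE-deficient BMDM, 3 with exosomes from wild-type BMDM and 3 with PBS. ApoE is the lipid carrier protein that macrophages secrete with cholesterol. All recipient cells were wild-type, and the exosome groups are labelled by the genotype of the donor cells. Whether the preparations also differed in other ways is not stated. Each library held 28581306 to 35929596 counts, and errors of CPM values are SD over 3 libraries. In a principal component analysis, the replicate 3 library of wild-type exosomes stood apart from the others on component 1, which held 15.2% of the variance, at 57.5 against -16.8 to 3.43. Without that library, 416 genes in place of 568 passed the threshold for wild-type exosomes against PBS, and 56 in place of 96 between the exosomes. Component 2, with 15.15% of the variance, set replicate 2 of wild-type exosomes at -45.4 and replicate 2 of ApoE-deficient exosomes at 38 apart from the others at -7.07 to 17.76. Without the former, 445 genes passed for wild-type exosomes against PBS and 59 between the exosomes. Without the latter, 421 passed for ApoE-deficient exosomes against PBS and 56 between the exosomes.

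Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188 in GRCm38) took 1.87% to 2.005% of the counts of every library. Its level was 18959 ± 376 CPM after ApoE-deficient exosomes, 19766 ± 364 CPM after wild-type exosomes and 19326 ± 654 CPM after PBS. None of the comparisons passed the threshold in edgeR, with log2 fold changes of -0.028 ± 0.023 (SE) for ApoE-deficient exosomes against PBS, 0.0325 ± 0.023 for wild-type exosomes against PBS and -0.060 ± 0.023 between the exosomes. The edgeR adjusted p values were 0.729, 0.607 and 0.384. With limma-voom, the difference between the exosomes passed (adjusted p = 0.0253). Between the exosomes the difference was -4.08%, with an unadjusted 95% interval of -7.15% to -0.91%.

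The comparison of ApoE-deficient exosomes with PBS asked which transcripts of wild-type macrophages differ after they receive these exosomes. Inflammatory genes, MHC class II genes and macrophage identity genes were lower. Interferon-stimulated genes were lower and lysosomal genes higher by camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.0623 and 0.163). Cx3cr1, the fractalkine receptor, chosen after its values were seen, fell from 306 ± 10.2 CPM to 194 ± 1.77 CPM, a log2 fold change of -0.65 ± 0.039 (SE; edgeR adjusted p = 2.76e-14). Thbs1, which encodes the matrix protein thrombospondin 1, fell from 284 ± 11.5 to 167 ± 6.11 CPM, and the complement component C1qa fell from 555 ± 7.44 to 402 ± 6.86 CPM. In all, 585 of 13815 genes passed the threshold, 252 higher and 333 lower. Most changes were small, with a median absolute log2 fold change of 0.25 among these genes, and 11 reached an absolute log2 fold change of 1, all of them lower.

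Among the 59 interferon-stimulated genes tested, 27 fell and none rose (38 fell when adjusted over the list alone). Ifit2, an interferon-induced RNA-binding protein, fell from 38.2 ± 6.21 to 22.3 ± 3.75 CPM, and Rtp4 fell by 0.55 on the log2 scale. Parp14 and Trim30a fell by 0.31 and 0.29. The list as a whole was lower (camera adjusted p = 1.48e-30), but with an estimated correlation the adjusted p was 0.0623. Its mean log2 scores were -0.25, -0.40 and -0.03 in the libraries of ApoE-deficient exosomes and 0.09 to 0.30 after PBS. Of 24 macrophage identity genes, 13 fell and 2 rose (16 and 3 when adjusted over the list alone; camera adjusted p = 5.47e-21, and adjusted p = 0.00319 with an estimated correlation). Those that fell included Fcgr1, an activating Fc receptor, at -0.58 ± 0.052, and Csf1r, the M-CSF receptor, at -0.28 ± 0.027. Gpnmb, a lysosome-associated glycoprotein, rose by 0.24 ± 0.024.

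Of 32 inflammatory cytokine and NF-kB target genes, 10 fell and none rose (16 fell when adjusted over the list alone; camera adjusted p = 1.13e-15, and adjusted p = 0.0115 with an estimated correlation). Marcksl1 fell by 0.88, Tnip3 by 0.62, Clec4e by 0.59 and the adhesion receptor Icam1 by 0.42. Of 12 MHC class II genes, 4 fell (5 when adjusted over the list alone; adjusted p = 0.0439 with an estimated correlation), namely Cd74 at -0.71 ± 0.083, H2-Aa at -0.83 ± 0.15, H2-Eb1 at -0.71 ± 0.17 and H2-Ab1 at -0.61 ± 0.14. Of 12 chemokines, 3 fell and 1 rose (5 and 1 when adjusted over the list alone; adjusted p = 0.0437 with an estimated correlation): Cxcl16, Ccl9 and Cxcl14 fell and Ccl3 rose by 0.34. Neutrophil markers, of which 8 were tested and none passed alone, were lower as a list (camera adjusted p = 0.00164; adjusted p = 0.228 with an estimated correlation), with mean log2 scores of -1.70, -0.24 and 0.19 in the libraries of ApoE-deficient exosomes and 0.41 to 0.73 after PBS.

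Lysosomal genes rose, 11 of 42, while 2 fell (18 and 4 when adjusted over the list alone; camera adjusted p = 3.8e-05, but adjusted p = 0.163 with an estimated correlation). Atp6v1a, a subunit of the proton pump, rose by 0.25 and the protease Ctsd by 0.16, while the proteases Ctsc and Ctsl fell by 0.42 and 0.23. Genes of cholesterol synthesis and uptake were higher as a list, with 2 of 24 past the threshold (2 when adjusted over the list alone; camera adjusted p = 0.00164, but adjusted p = 0.0623 with an estimated correlation). Heat shock proteins were higher, with Ahsa1 and Hspd1 of 14 past the threshold (3 when adjusted over the list alone; camera adjusted p = 0.00216, but adjusted p = 0.0623 with an estimated correlation). The unfolded protein response was higher with Edem1 and Hspa5 of 20 (5 when adjusted over the list alone; camera adjusted p = 0.00655, but adjusted p = 0.27 with an estimated correlation).

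Of 20 immediate early genes, 6 fell, Fos and Nr4a1 among them, and 1 rose (8 and 2 when adjusted over the list alone; camera adjusted p = 6.31e-05, but adjusted p = 0.08 with an estimated correlation). Of 16 MHC class I genes, H2-K1, B2m, Tapbp and H2-Q4 fell (6 when adjusted over the list alone; camera adjusted p = 0.000311, but adjusted p = 0.27 with an estimated correlation). Of 14 targets of the microRNA miR-146a-5p, 2 fell, Notch1 among them (6 when adjusted over the list alone; camera adjusted p = 0.00101, but adjusted p = 0.0581 with an estimated correlation). In the list of LXR targets, which include cholesterol efflux genes, Abca1, Pltp and Lpl fell and Npc1 rose among 18 (3 and 2 when adjusted over the list alone; camera adjusted p = 0.0141, but adjusted p = 0.266 with an estimated correlation). Mitosis genes were lower as a list with none of 41 past the threshold (0 when adjusted over the list alone; camera adjusted p = 0.00844, but adjusted p = 0.364 with an estimated correlation). The camera call of the LXR targets ended without replicate 3 of ApoE-deficient exosomes (adjusted p = 0.0536) or of PBS (adjusted p = 0.146), and that of the mitosis genes without replicate 1 of ApoE-deficient exosomes (adjusted p = 0.151) or replicate 2 of PBS (adjusted p = 0.128).

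By the rule for named genes, the larger increases were Rapgef3, an exchange factor activated by cyclic AMP, at 0.79 ± 0.23, the thyroid hormone deiodinase Dio2 at 0.69 ± 0.14, and Rps6ka2, Gprc5b, Mamdc2, Mrgpre, Rhov, Fam198b, Tbc1d2 and Tacc2 at 0.54 to 0.62. The larger decreases were Pilra, an inhibitory receptor, at -1.47 ± 0.23, the membrane protease Mmp14 at -1.30 ± 0.21, Tmem176a at -0.97 ± 0.14, Marcksl1, Ifit3, Tmem176b, H2-Aa, Cmklr1, Dmpk and Rhobtb1, the last at -0.81 ± 0.20. Exons of other genes overlap 15.1% of the exon length of Pilra, 13.1% of Gprc5b and 9.3% of Rapgef3. The calls of 13 of these 20 genes held under every alternative run. The others ended without at least 1 library. Without replicate 2 of ApoE-deficient exosomes the edgeR adjusted p was 0.196 for Rapgef3, 0.0988 for Ifit3, 0.0735 for Mrgpre and 0.0903 for Rhobtb1. The call of Rapgef3 also ended with limma-voom (adjusted p = 0.111). The edgeR adjusted p was 0.0624 for Rhov without replicate 1 of ApoE-deficient exosomes, 0.139 for Cmklr1 without replicate 3 of PBS and 0.157 for Tacc2 without replicate 2 of PBS. Among list members, the calls of Hspd1, Ccl3, Cxcl14, Lpl, Npc1, Pltp, Notch1, Nr4a1, H2-Ab1, H2-Eb1, H2-K1, B2m, Tapbp and H2-Q4 also ended without at least 1 library, the highest edgeR adjusted p among these being 0.261 for Lpl without replicate 1 of ApoE-deficient exosomes.

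The comparison of wild-type exosomes with PBS asked what exosomes from unmodified donors do to the same recipient cells. Cholesterol synthesis genes and the selenoprotein genes Gpx1, Selenow and Selenoh were higher, and inflammatory genes and macrophage identity genes were lower. Selenoproteins were not among the lists fixed beforehand, and not all rose. Of those chosen after their values were seen, Gpx3 and Selenom were higher, Selenom at 0.54 (edgeR adjusted p = 0.00109). Sephs2 was lower at -0.25 (edgeR adjusted p = 0.00722), and so was the selenoprotein Txnrd1, given below with the NRF2 targets. By camera with the preset correlation, lysosomal genes were higher and amino acid response genes and NRF2 targets lower, but not with an estimated correlation (adjusted p = 0.0764, 0.051 and 0.19). Gpx1 (ENSMUSG00000063856, chromosome 9, 108338903 to 108340343), a selenium-dependent glutathione peroxidase, rose from 393 ± 15.6 to 561 ± 9.54 CPM, a log2 fold change of 0.51 ± 0.035 (edgeR adjusted p = 7.95e-13; chosen after its values were seen). Cx3cr1 fell from 306 ± 10.2 to 199 ± 3.32 CPM (-0.62 ± 0.039). In all, 568 genes passed the threshold, 267 higher and 301 lower, with a median absolute log2 fold change of 0.25, and 15 reached an absolute log2 fold change of 1.

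Of 42 lysosomal genes, 16 rose and 2 fell (20 and 3 when adjusted over the list alone; camera adjusted p = 1.65e-09, but adjusted p = 0.0764 with an estimated correlation). The proteases Ctsd and Ctsb rose by 0.25 ± 0.023 and 0.19 ± 0.022, Psap, the precursor of saposins, rose by 0.22 ± 0.025, and Ctsc fell by 0.36. Of 24 genes of cholesterol synthesis and uptake, 3 rose and none fell (11 rose when adjusted over the list alone; camera adjusted p = 4.76e-08, and adjusted p = 0.039 with an estimated correlation). Among them, Insig1 was at 0.38 ± 0.094 and the transcription factor Srebf2 at 0.20 ± 0.055. The unfolded protein response was higher with Hspa5, Edem1 and Hyou1 of 20 past the threshold (6 when adjusted over the list alone; camera adjusted p = 0.0022, but adjusted p = 0.19 with an estimated correlation). The TCA cycle was higher with Mdh2 of 23 (2 when adjusted over the list alone; camera adjusted p = 0.0251, but adjusted p = 0.195 with an estimated correlation). Nuclear-encoded oxidative phosphorylation was higher with Ndufa4 and Uqcr10 of 72 (0 when adjusted over the list alone; camera adjusted p = 0.0417, but adjusted p = 0.28 with an estimated correlation).

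Of 20 amino acid response genes, the targets of the transcription factor ATF4, 5 fell and none rose (7 fell and 1 rose when adjusted over the list alone; camera adjusted p = 4.07e-07, but adjusted p = 0.051 with an estimated correlation). Mthfd2, a mitochondrial folate enzyme, fell from 20.4 ± 1.63 to 9.88 ± 3.13 CPM (-1.04 ± 0.15), Asns, asparagine synthetase, fell by 0.73, Atf5 by 0.34 and Atf4 itself by 0.32. Of 22 NRF2 antioxidant targets, 7 fell and none rose (11 fell and 2 rose when adjusted over the list alone; camera adjusted p = 8.67e-09, but adjusted p = 0.19 with an estimated correlation). The heme oxygenase Hmox1 fell by 0.32 ± 0.033, Pgd by 0.26, the thioredoxin reductase Txnrd1 by 0.20 and G6pdx by 0.17. Inflammatory and NF-kB target genes fell, 10 of 32, with none higher (10 when adjusted over the list alone; camera adjusted p = 1.77e-08, and adjusted p = 0.039 with an estimated correlation), among them Nfkbiz at -0.66, Tnip3 at -0.54, Nfkbie at -0.47 and Marcksl1 at -0.43. Of 24 macrophage identity genes, 9 fell and 2 rose (12 and 3 when adjusted over the list alone; camera adjusted p = 1.23e-06, and adjusted p = 0.039 with an estimated correlation). Cd14, the endotoxin coreceptor, fell by 0.36, C1qa by 0.28 and Csf1r by 0.22, and Gpnmb rose by 0.22.

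Immediate early genes were lower as a list, with Fos, Junb and Zfp36 lower and Jun higher among 20 (7 and 2 when adjusted over the list alone; camera adjusted p = 0.00343, but adjusted p = 0.19 with an estimated correlation). Interferon-stimulated genes were lower with Rtp4 of 59 past the threshold (0 when adjusted over the list alone; camera adjusted p = 0.0127, but adjusted p = 0.593 with an estimated correlation). MHC class II genes were lower with Cd74 of 12 past the threshold (2 when adjusted over the list alone; camera adjusted p = 0.025, but adjusted p = 0.19 with an estimated correlation). Without replicate 2 of PBS, camera gave adjusted p = 0.326 for the interferon-stimulated genes, 0.106 for oxidative phosphorylation and 0.0589 for MHC class II. The MHC class II call also ended without replicate 3 of PBS (camera adjusted p = 0.0844) or of wild-type exosomes (0.09). The camera call of oxidative phosphorylation without replicate 1 of PBS (0.116) or replicate 2 of wild-type exosomes (0.118), the TCA cycle without replicate 1 of PBS (0.141) and the immediate early genes without replicate 3 of PBS (0.0716).

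By the rule for named genes, the larger increases were Rapgef3 at 1.07 ± 0.23, Fam83h at 0.86 ± 0.23, Nkain1 at 0.80 ± 0.22, the selenoproteins Selenow at 0.80 ± 0.085 and Selenoh at 0.79 ± 0.20, Brca2, Cnrip1, the interleukin 1 receptor antagonist Il1rn at 0.66 ± 0.16, Gprc5b and Rps6ka2. The larger decreases were Mthfd2, Pilra at -1.04 ± 0.22, the C-type lectin Clec4a1 at -0.81 ± 0.096, Aldh18a1, an enzyme of proline synthesis, at -0.80 ± 0.14, Hexdc, Tmem176a, Asns, Oxnad1, Tmem176b and Cep83os. The calls of 11 of these 20 genes held under every alternative run. Those of the other genes ended without at least 1 library. Without replicate 3 of wild-type exosomes the edgeR adjusted p was 0.168 for Fam83h, 0.153 for Hexdc, 0.125 for Cnrip1, 0.122 for Brca2 and 0.0767 for Il1rn. The edgeR adjusted p was 0.126 for Selenoh without replicate 2 of wild-type exosomes, while it was 0.256 for Oxnad1, 0.182 for Nkain1 and 0.0827 for Cep83os without replicates 1, 2 and 3 of PBS in that order. The call of Oxnad1 also ended with limma-voom (adjusted p = 0.0508) and in edgeR with only the 6 libraries compared (adjusted p = 0.0517). Among list members, the calls of Insig1, Srebf2, Edem1, Hyou1, G6pdx, Ndufa4, Uqcr10 and Rtp4 also ended without at least 1 library, the highest edgeR adjusted p being 0.272 for Srebf2 without replicate 2 of PBS.

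The direct comparison of the exosomes asked what differs with the ApoE genotype of the donor cells. After ApoE-deficient exosomes, genes of the amino acid response were higher than after wild-type exosomes, and the selenoprotein genes Gpx1, Selenow and Gpx3 were lower. NRF2 targets were higher and interferon-stimulated genes lower by camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.109 and 0.127). Against PBS at the preset correlation, neither the amino acid response nor the NRF2 list passed camera with ApoE-deficient exosomes (adjusted p = 0.125 and 0.191). With wild-type exosomes both lists were lower than after PBS by that test. Mthfd2 (ENSMUSG00000005667, chromosome 6, 83305691 to 83325908) was 25.5 ± 3.44 CPM after ApoE-deficient and 9.88 ± 3.13 CPM after wild-type exosomes, a log2 fold change of 1.37 ± 0.15 (edgeR adjusted p = 3.12e-07). Gpx1 was 336 ± 7.82 against 561 ± 9.54 CPM, a log2 fold change of -0.74 ± 0.035 (edgeR adjusted p = 1.64e-17). In all, 96 genes passed the threshold, 39 higher and 57 lower, and 3 of them reached an absolute log2 fold change of 1. This count fell to 52 without the replicate 1 library of ApoE-deficient exosomes, 56 without its replicate 2, and 59 and 56 without replicates 2 and 3 of wild-type exosomes, while DESeq2 called 150.

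Of 20 ATF4 targets, 4 were higher after ApoE-deficient exosomes and none lower (7 higher when adjusted over the list alone; camera adjusted p = 2.96e-18, and adjusted p = 0.0169 with an estimated correlation). They were Mthfd2, Asns at 1.19 ± 0.14, Atf5 at 0.56 ± 0.071 and Atf4 at 0.51 ± 0.052. By the rule for named genes, Aldh18a1, the arginine transporter Slc7a1 and the aminoacyl-tRNA synthetases Cars, Yars, Aars and Mars were also higher, at 0.35 to 0.89. Exons of other genes overlap 15.1% of the exon length of Aars. Of 22 NRF2 targets, 7 were higher and none lower (14 higher when adjusted over the list alone; camera adjusted p = 4.7e-21, but adjusted p = 0.109 with an estimated correlation), with Txnrd1 at 0.28 ± 0.040, Pgd at 0.26 ± 0.032, the peroxiredoxin Prdx1 at 0.21 ± 0.037 and Hmox1 at 0.21 ± 0.033. Hmox1 was nevertheless lower than after PBS with ApoE-deficient exosomes too, at -0.135 to -0.078 over the alternatives. That call ended in 5 of 14 of them.

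The selenoproteins Selenow (ENSMUSG00000041571, chromosome 7, 15917208 to 15922402) and Gpx3, a secreted glutathione peroxidase, were lower together with Gpx1. Selenow was 32.9 ± 0.53 against 65.7 ± 5.82 CPM (edgeR adjusted p = 9.17e-10), and Gpx3 48.3 ± 1.64 against 70.2 ± 5.31 CPM (-0.54 ± 0.072). After PBS, the libraries had 46.7 to 49.8 CPM of Gpx3, close to its level after ApoE-deficient exosomes. Of 59 interferon-stimulated genes, 7 were lower and none higher (32 lower when adjusted over the list alone; camera adjusted p = 1.53e-26, but adjusted p = 0.127 with an estimated correlation). Ifit2 was at -0.58 ± 0.12, Ifi27l2a at -0.52 ± 0.10, Stat2 at -0.31 ± 0.057 and Parp14 at -0.19 ± 0.041. The libraries were uneven, with mean log2 scores of the interferon list of -0.25, -0.40 and -0.03 in replicates 1, 2 and 3 of ApoE-deficient exosomes. After wild-type exosomes they were 0.02 to 0.09. Of 24 macrophage identity genes, 4 were lower and none higher (5 lower when adjusted over the list alone; camera adjusted p = 1.36e-07, and adjusted p = 0.032 with an estimated correlation), namely Fcgr1 at -0.39 ± 0.052 and the complement genes C1qa, C1qc and C1qb at -0.18, -0.18 and -0.15. Of 38 DNA replication genes, Mcm6 alone was lower (5 lower when adjusted over the list alone), and the list was lower (camera adjusted p = 8.13e-05, and adjusted p = 0.0495 with an estimated correlation).

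Of 21 extracellular matrix genes, Thbs1, Mmp14 and Cd44 were lower (4 when adjusted over the list alone; camera adjusted p = 0.00345, but adjusted p = 0.162 with an estimated correlation). MHC class I genes were lower with H2-K1 of 16 past the threshold (2 when adjusted over the list alone; camera adjusted p = 0.00013, but adjusted p = 0.256 with an estimated correlation). Lysosomal genes were lower as a list, with Grn and Ctsb lower and Lipa higher among 42 (5 and 1 when adjusted over the list alone; camera adjusted p = 0.0367, but adjusted p = 0.386 with an estimated correlation). Inflammatory genes were lower as a list, with Marcksl1 lower and Tnfaip2 higher among 32 (3 and 1 when adjusted over the list alone; camera adjusted p = 0.013, but adjusted p = 0.249 with an estimated correlation).

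The remaining lists that were lower by camera had no member past the threshold. Mitosis, with 41 genes, was among them (0 when adjusted over the list alone; camera adjusted p = 0.00245, but adjusted p = 0.256 with an estimated correlation). Others were MHC class II with 12 (3 when adjusted over the list alone; camera adjusted p = 0.012), cholesterol synthesis and uptake with 24 (1 when adjusted over the list alone; camera adjusted p = 0.013) and chemokines with 12 (0 when adjusted over the list alone; camera adjusted p = 0.0334). The last 3 each had an adjusted p = 0.162 with an estimated correlation. Neutrophil markers, with none of 8 past the threshold (0 when adjusted over the list alone), were also lower as a list (camera adjusted p = 0.00848, but adjusted p = 0.256 with an estimated correlation), and their mean log2 scores were 0.58, -0.09 and -0.41 in the libraries of wild-type exosomes. Without replicate 1 of ApoE-deficient exosomes, camera gave adjusted p = 0.0685 for cholesterol synthesis, 0.121 for chemokines, 0.103 for mitosis and 0.148 for neutrophil markers. Without replicate 2 of wild-type exosomes it gave 0.0613 for cholesterol synthesis, 0.126 for inflammatory genes, 0.126 for chemokines, 0.0814 for lysosomal genes and 0.0657 for extracellular matrix genes. Without replicate 1 of wild-type exosomes it gave 0.0889 for MHC class II, 0.0941 for chemokines, 0.0941 for neutrophil markers and 0.0569 for lysosomal genes, whose call also ended without replicate 2 of ApoE-deficient (0.124) or replicate 3 of wild-type exosomes (0.0553).

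The remaining named genes were Mmp14 at -1.08 ± 0.21, Ms4a4a, Aoah, Irf7 and Marcksl1, all lower. Of the 20 named genes, 11 held their calls under every alternative run. Calls of the other genes ended without single libraries. The edgeR adjusted p was 0.344 for Irf7 without replicate 1 of ApoE-deficient exosomes, and 0.21 for Aoah, 0.145 for Ifit2 and 0.057 for Ifi27l2a without its replicate 2. The edgeR adjusted p was also 0.218 for Slc7a1 without replicate 1 of wild-type exosomes, 0.164 for Ms4a4a, 0.0862 for Mmp14 and 0.0708 for Marcksl1 without its replicate 2, and 0.256 for Mars without its replicate 3. Among list members, the calls of Parp14, C1qb, Mcm6, Cd44, H2-K1, Grn, Ctsb and Lipa also ended without at least 1 library, the highest edgeR adjusted p being 0.422 for Mcm6 without replicate 1 of ApoE-deficient exosomes.

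**Figure D1:**
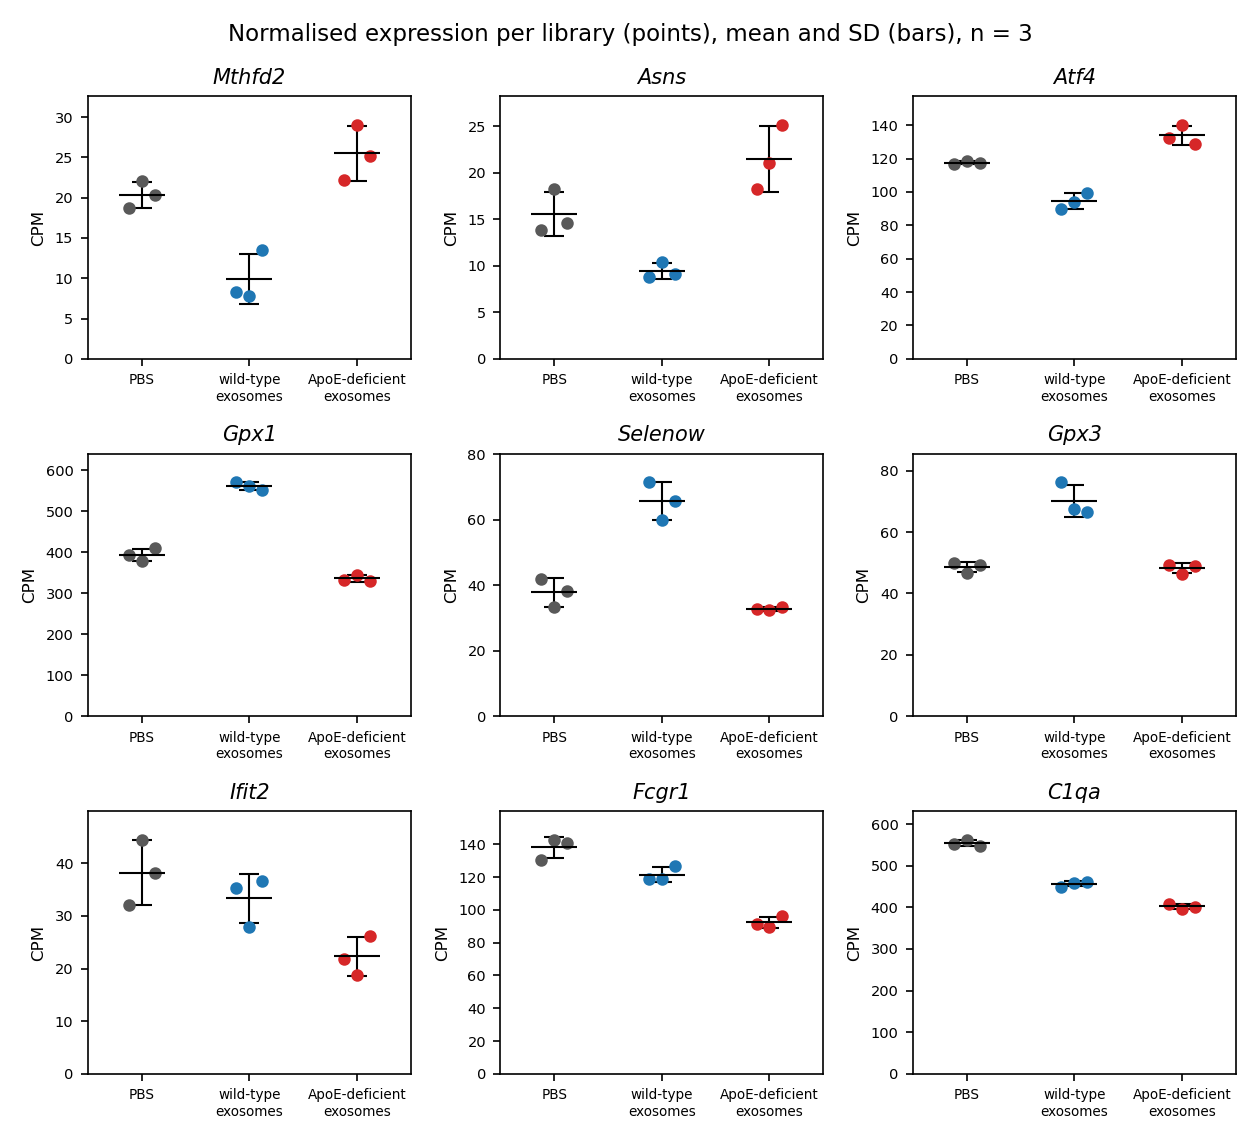
Normalised expression (CPM, linear axis from 0) of 9 genes in each library, by group; points are libraries, horizontal bars the mean and vertical bars the SD (n = 3). Gpx1 lay at 393 CPM after PBS, 561 after wild-type and 336 after ApoE-deficient exosomes, and Mthfd2 at 20.4, 9.88 and 25.5.

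Calls against PBS overlapped between the exosome treatments. Of the 585 and 568 genes called, 169 were higher with both, 158 were lower with both and 4 went in opposite directions. Independent lists of these sizes would share 4.87 and 7.26. Simulated groups with no effect, set against shared PBS libraries, gave a mean of 0.05 genes higher and 0 lower with both, but they had at most 2 calls per direction and so show chance without any effect, not the overlap of lists this long. The PBS libraries were too few to be split, so part of the excess may come from the shared controls. Genes called with both included Anpep, an aminopeptidase, and the lectin Lgals3, each chosen after its values were seen. Anpep rose by 0.37 ± 0.028 with ApoE-deficient and 0.39 ± 0.028 with wild-type exosomes, and Lgals3 by 0.29 ± 0.028 and 0.29 ± 0.028. Fold changes against PBS correlated at 0.478 across genes, which are not independent replicates, against 0.503 in the simulations (range 0.4695 to 0.5433), and their covariance was 0.1125 against 0.0892 (range 0.0794 to 0.0994). Of 822 genes called with at least 1 treatment, 73 also differed between the exosomes, and 23 of the 96 genes that differed between the exosomes were called with neither treatment against PBS.

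**Figure D2:**
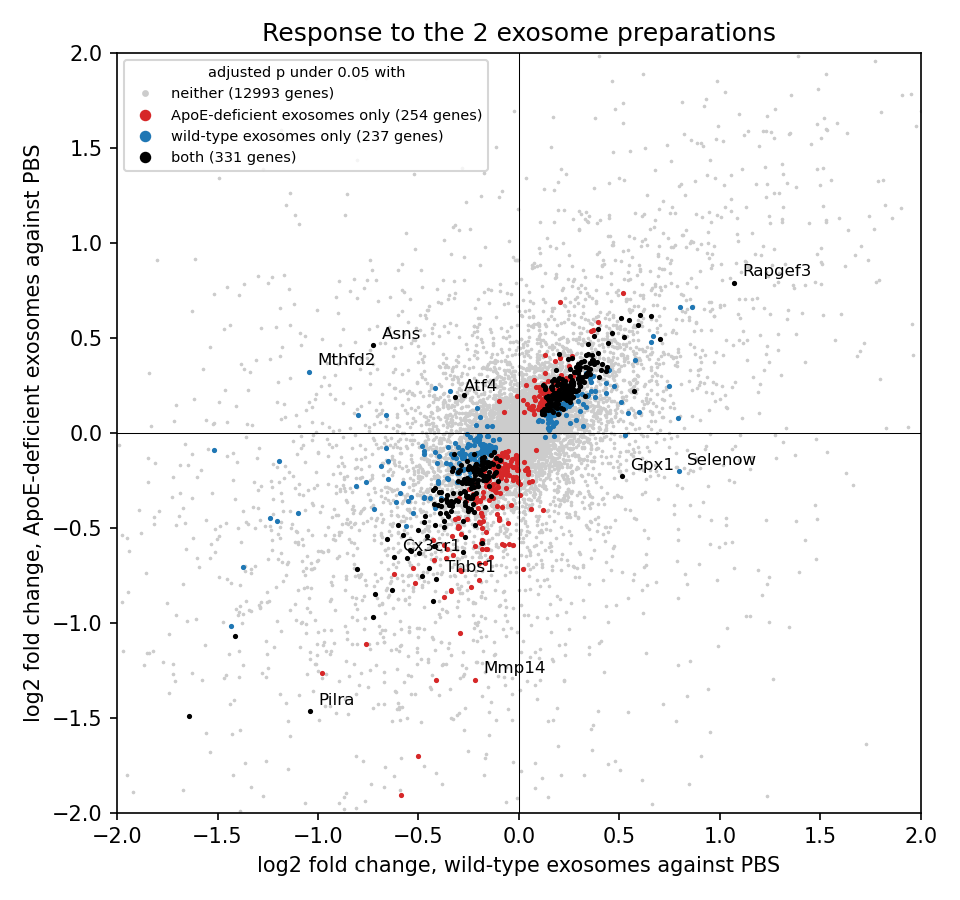
Log2 fold change against PBS for wild-type exosomes (horizontal axis) and ApoE-deficient exosomes (vertical axis), each point a gene, coloured by the comparison in which its edgeR adjusted p was under 0.05; 212 genes outside the axes, 4 of them called, are not drawn. The 331 genes called with both have the same sign on both axes, except Asns, Atf4, Aars and Gpx1.

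Of the 36 lists tested, 21 passed camera in at least 1 comparison and 15 in none, the lowest adjusted p of these 15 being 0.113. The latter were glycolysis, mitochondrially encoded mRNAs, fatty acid oxidation, fatty acid synthesis, alternative activation, hypoxia, cytosolic ribosomal proteins, and the markers of monocytes and progenitors, dendritic cells, B cells, erythroid cells, megakaryocytes, fibroblasts, endothelium and osteoclasts. Glycolysis, for example, had a median log2 fold change of 0.025 over 23 genes after ApoE-deficient exosomes against PBS (camera adjusted p = 0.237), with Hk3 as the member past the threshold. Median, mean and test differed in sign for several of these 15 lists, such as the B cell and osteoclast markers after ApoE-deficient exosomes.

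**Figure D3:**
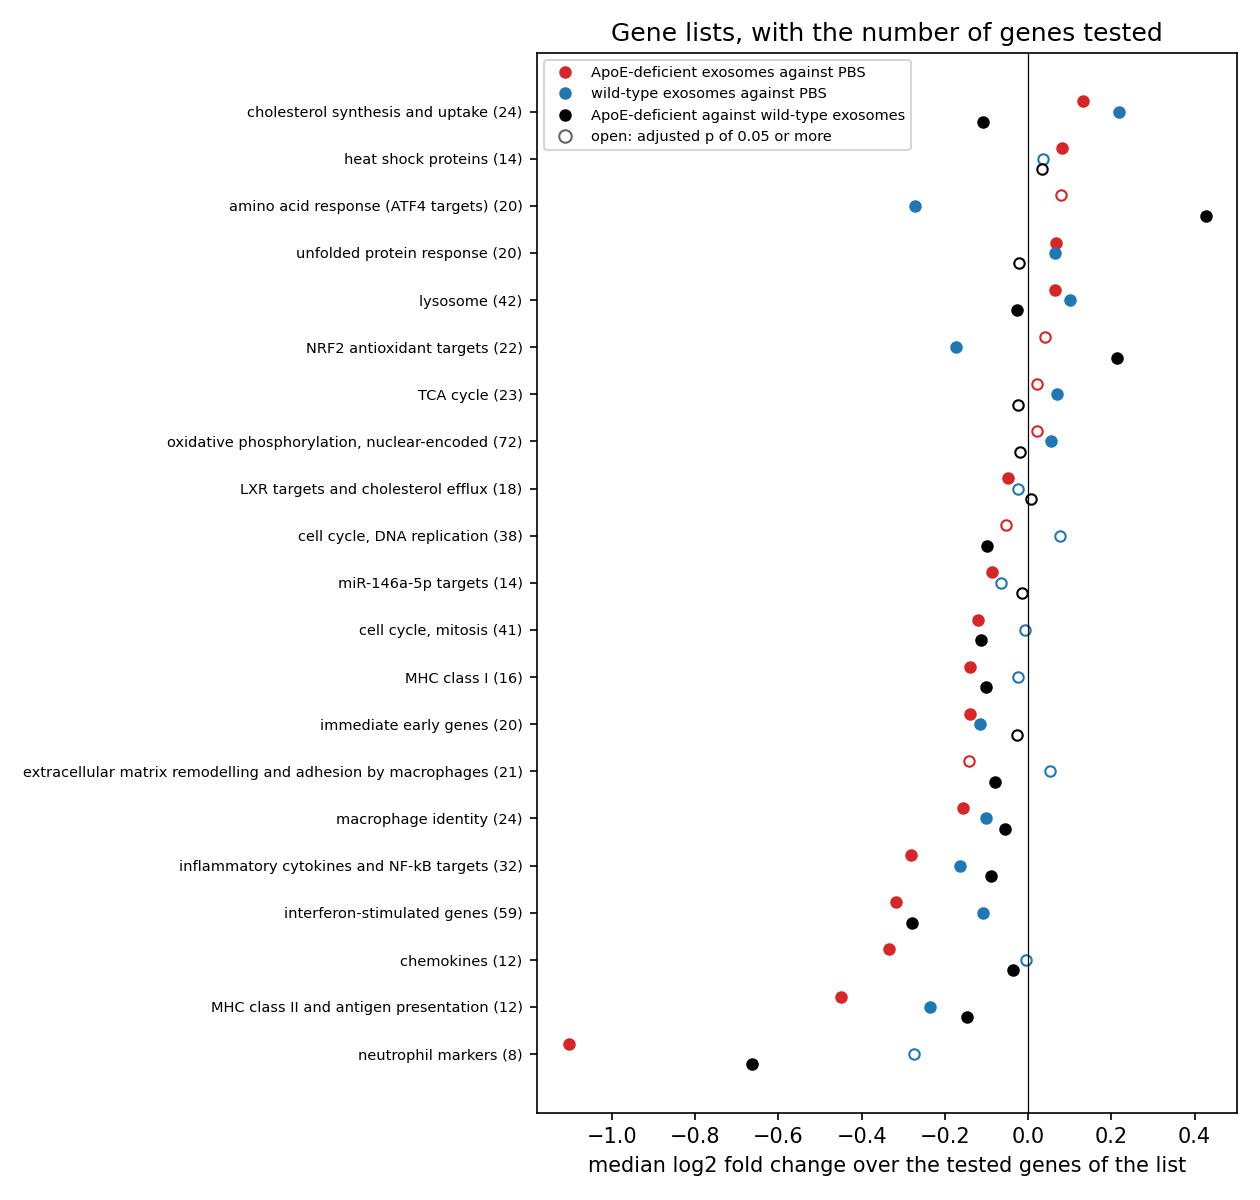
Median log2 fold change (horizontal axis) of the 21 lists that passed camera in at least 1 of the 3 comparisons, with the number of genes tested in brackets; filled points have a camera adjusted p under 0.05 at the preset correlation and open points do not. ATF4 targets lie at -0.27 for wild-type exosomes against PBS and at 0.43 between the exosomes.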

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

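Asns, Aars, Atf4 and Gpx1 moved in opposite directions against PBS with the exosomes of the different donors, and the difference was tested directly between the exosomes. The tests of a single library behind the ATF4 targets and of the synthetases without Mars were chosen after the result was seen. Asns was at 0.46 ± 0.14 with ApoE-deficient and -0.73 ± 0.14 with wild-type exosomes, a difference of 1.19 (edgeR adjusted p = 2.11e-06). Aars was at 0.20 ± 0.053 and -0.28 ± 0.053, a difference of 0.48 (edgeR adjusted p = 3.31e-07). Atf4 was at 0.19 ± 0.051 and -0.32 ± 0.052, a difference of 0.51 (edgeR adjusted p = 6.97e-08). Gpx1 was at -0.23 ± 0.035 and 0.51 ± 0.035, a difference of -0.74 (edgeR adjusted p = 1.64e-17). The increases against PBS with ApoE-deficient exosomes were the weaker side: Asns had an edgeR adjusted p of 0.0498, and without single libraries the edgeR adjusted p rose to 0.396 for Asns (without replicate 3 of ApoE-deficient exosomes), 0.191 for Atf4 (without its replicate 2) and 0.161 for Aars (without replicate 2 of PBS). The call of Asns also ended with DESeq2 (adjusted p = 0.0521), and in edgeR with DESeq2 size factors (adjusted p = 0.0508) or total counts (adjusted p = 0.0593).

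Asns, Aars and Atf4 belong to the amino acid response, and the ATF4 target list was higher after ApoE-deficient than after wild-type exosomes; a single library was argued against, since the highest camera adjusted p of the list without each of the 6 libraries was 1.7e-11. If a wider amino acid response was the reason, other cytosolic aminoacyl-tRNA synthetases should also be higher, with a median above 0.05 by the bound set in advance. The median of 17 of them, 0.017 ± 0.042 (SE over genes), cannot be told apart from this bound. That outcome depends on Mars, which the rule for named genes gave as higher. Without Mars the median of 0.0064 ± 0.039 lay under the bound by more than its SE. Mars had the highest of the 17 values, 0.35, so leaving it out could not raise the median. The 17 also leave out Cars, Yars and Aars, which the rule gave as higher, and this choice could not raise the median either. A low median of the 17 therefore cannot argue against a wider response, and no conclusion is drawn from it. Against PBS, for which no bound was set, the median of the 17 was 0.11 ± 0.027 with ApoE-deficient and 0.027 ± 0.040 with wild-type exosomes. Between the exosomes, Eprs, Mars, Nars and Sars of these 17 were higher and none lower (7 higher when adjusted over the list alone). Each of these 4 calls ended without at least 1 library, the highest edgeR adjusted p being 0.264 for Nars without replicate 3 of ApoE-deficient exosomes. A different nutrient content of the exosome preparations, a different state of the culture medium and an effect of donor ApoE all stay open, as untested.

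Gpx1 and Selenow were at 561 and 65.7 CPM after wild-type exosomes, 393 and 37.9 CPM after PBS, and 336 and 32.9 CPM after ApoE-deficient exosomes. Transcript length and GC content were argued against, since 95.7% or more of the log2 fold change of both genes was left after subtracting the median of 200 genes matched on both, and so was a single library, with a highest edgeR adjusted p of 3.23e-07 without each of the 6. Gpx1, Selenow and Gpx3 contain selenocysteine, and their mRNAs are known to fall when selenium is short, so a different selenium supply is a candidate explanation. Of 3 further selenium-sensitive mRNAs, chosen before their difference between the exosomes was seen, the median was -0.44 ± 0.26 (SE over the 3 genes). Selenom was lower at -0.44 (edgeR adjusted p = 0.0402, but 0.0591 to 0.324 when any of the 6 libraries was left out). Selenoh was at -0.71 (edgeR adjusted p = 0.101, but 0.0213 without the low-count filter) and Msrb1 at 0.0064. This is not an independent check, since Selenoh and Selenom were higher with wild-type exosomes against PBS (0.79 and 0.54) and the same wild-type libraries enter here. With ApoE-deficient exosomes against PBS they were at 0.077 and 0.11, and neither passed the threshold. The median of 8 selenoprotein mRNAs that are kept when selenium is short was 0.074 ± 0.063, with 1 higher and 2 lower when adjusted over the list alone. A difference in selenium stays open as a candidate, since Msrb1 did not follow and the selenoprotein Txnrd1 was higher at 0.28 (edgeR adjusted p = 3.48e-05). The median of 4 other selenoproteins was 0.13 ± 0.14, with 3 above 0 and 1 below. Among these 4, Dio2 was at 0.49 (edgeR adjusted p = 0.118) and was higher when adjusted over the list alone. Whether a difference in selenium would come from the exosomes, from serum carried with them or from donor ApoE was not tested.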

How the results depend on the processing

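Counts against PBS stayed within 1.5 times the reported ones under every alternative. When a library was left out, they were 421 to 509 genes for ApoE-deficient exosomes and 408 to 536 for wild-type exosomes. The test over all groups then called 538 to 708 genes, against 730 as reported. Between the exosomes, leaving out a library gave 52 to 101 genes, 21 to 46 higher and 31 to 67 lower. The count was 52 without replicate 1 of ApoE-deficient exosomes, 56 without its replicate 2, and 59 and 56 without replicates 2 and 3 of wild-type exosomes. These fits had fewer samples. DESeq2 called 150 genes, 59 higher and 91 lower, and shared 95 of the 96 calls; with a mean of at least 5 CPM, 59 genes were higher. The cause of these increases was not tested. Scaling moved the share of higher against lower calls by under 10 percentage points.

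Over all genes, correlations of the libraries showed no pairing by replicate number. Deviations from the group means correlated at -0.035 to 0.04 for the 9 pairs with the same number and at -0.048 to 0.039 for the 18 others, and not every library correlated best with its own number. With the number as a block, counts rose from 585, 568 and 96 to 662, 669 and 144, the last with 64 higher and 80 lower. Of the reported calls, 99.5%, 99.5% and 100% were shared. Since the block raised the counts, a pairing that affects part of the genes stays open.

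Gene list calls depended on the correlation assumed between genes. Against 15, 12 and 14 lists with the preset value, an estimated correlation left 4 for ApoE-deficient exosomes against PBS, 3 for wild-type exosomes against PBS and 3 between the exosomes, and fry gave 10, 15 and 6. Leaving out a library gave 14 to 16, 9 to 13 and 10 to 16 lists. Over all alternatives, 312 of 3224 values of named genes and 75 of 1080 values of lists lost a call, while 3 and 21 gained one. Both totals include genes and lists not called as reported, which had no call to lose. The share of calls lost was therefore larger than these totals give. Between the exosomes, Apoe gained its call with limma-voom (adjusted p = 0.0253), and Selenoh without the low-count filter and with the block (edgeR adjusted p = 0.0213 and 0.0296). Apoe, not called against PBS with ApoE-deficient exosomes, ranged from -0.0462 to 2e-04 without single libraries, the latter without replicate 3 of PBS. Msrb1, not called between the exosomes, ranged from -0.0587 to 0.0384: it went from 0.0064 to -0.0587 without replicate 1 of ApoE-deficient exosomes, and to -0.0067 and -0.0086 without replicates 2 and 3 of wild-type exosomes. The cause was not tested. At this depth, simulated changes of 1.2-fold were recovered in 32% to 54% of genes, so smaller changes can be missed.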

Other observations

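The tests of endotoxin response genes and of the NF-kB list as a sign of endotoxin were chosen after the results were seen, and so were the genes C3, Clec4a1 in the comparison with ApoE-deficient exosomes, and Il1b. The complement component C3 was at -0.75 ± 0.054 with ApoE-deficient exosomes (edgeR adjusted p = 1.99e-12), and Clec4a1, a lectin receptor, was at -0.72 ± 0.095 with ApoE-deficient and -0.81 ± 0.096 with wild-type exosomes. Il1b, at 3.80 ± 0.71 CPM after PBS and 1.00 ± 0.36 CPM after ApoE-deficient exosomes, was at -1.91 ± 0.36 (edgeR adjusted p = 0.000498), and its difference between the exosomes was short of the threshold (edgeR adjusted p = 0.0841).

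Many genes changed alike with both exosomes. Length and GC content were argued against, since at least 87.1% of the median of the lysosome and macrophage identity lists was left after subtracting that of matched genes. Shared PBS libraries alone, with no effect of the exosomes and noise as simulated, were argued against for the called genes. With both exosomes 169 genes were higher and 158 lower, against at most 1 and 0 in the simulations. A shift of the PBS libraries as a group was not simulated. Over all genes, the simulations did not decide whether the shared libraries gave the likeness. The covariance of the fold changes, 0.1125, lay above every value simulated without an effect (0.0794 to 0.0994). A covariance also grows with the noise, so noise larger than that simulated would raise it. The correlation, 0.478, which effects of only 1 treatment lower, lay within its simulated range of 0.4695 to 0.5433. Endotoxin in the preparations stays open, since the median of 12 endotoxin response genes was -0.42 ± 0.31 (SE) with ApoE-deficient and 0.019 ± 0.22 with wild-type exosomes, with Ccl3 higher with both (0.34 and 0.30; edgeR adjusted p = 0.0147 and 0.0422, calls that ended in 3 and 8 of 14 alternatives, the latter whenever 1 of the 6 libraries was left out, with edgeR adjusted p up to 0.158) and Clec4e lower with both (-0.59 and -0.43), while the NF-kB target list, which leaves out Ccl3, was lower with both (highest camera adjusted p = 0.039 with an estimated correlation). An effect of taking up any vesicle, whatever its donor, stays open as untested, since no group received vesicles from another cell type.

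Chance was examined by regrouping the libraries. The test over all 3 groups called 730 genes, and the highest of 99 other groupings drawn gave 392. Only the real grouping, itself 1 of the 100 splits, reached its count, so the share was under 0.05. This counts against chance only if the libraries are independent, and whether mice and exosome preparations were separate is not stated. For the pairs of groups, 10 splits are too few for a share under 0.05: the real counts were 585, 568 and 96 genes, and the highest of the other splits gave 2, 0 and 1. For gene lists the real counts were 15, 12 and 14, and the highest of the other splits gave 8, 8 and 6. In each of these, 1 of the 10 splits reached the real value.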
